A study of Mus musculus with 11 samples.

How the data were processed

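RNA from mouse cardiac progenitor cells and from C2C12, a mouse myoblast line that forms muscle fibres in culture, was measured on 11 Agilent 1-colour arrays. Per the labels, the progenitors came from the atrium, ventricle or aorta of wild-type mice (WT, 3 arrays) or of mice null for beta-sarcoglycan (KO, 5 arrays). C2C12 cells (3 arrays) were the control for muscle differentiation. The labels do not say which arrays came from separate mice or cultures, so the p-values measure the spread between these samples, which may be technical. For KO with WT it is a spread between regions of the heart. After near-identical arrays were averaged, the samples of each genotype each came from a different region. They also do not give the age of the mice, the passage of the cells or whether the cells were growing or differentiating at harvest.

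The deposited scanner values are spot intensity values from Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes. Per the file headers, the software subtracted the background, removed spatial trends within each array and put surrogate values in place of signals near background, with no scaling between arrays. The deposited series-wide table holds log2 values. Set against the scanner values, its columns equalled log2 of the mean processed signal per probe within 0.01 for 99.7 to 99.8% of probes on every array. It therefore carried no further scaling or centring, and its column medians ran from 5.45 to 5.77. Each array held 45018 spots, of which 1639 were controls and were left out. Spots marked as non-uniform or as population outliers were also left out (39 to 120 per array), and no spot was saturated. The repeated spots of a probe were averaged. The array-wide 75th percentile of signal ran from 962.8 to 1145.6 and the median from 43.6 to 54.6. Between 49 and 62% of probes were well above background, and the number of arrays limits the precision.

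Of 41174 probes, 53 with no unmarked spot on some array were left out, which left 41121. Probe names were updated through the accession for 24348 probes, the symbol for 6293 and a synonym for 2419, in a RefSeq gene table of assembly GRCm38.p6. For 8061 probes the name in the scanner output was kept. Probe positions are those of the array design, on mouse build mm8 per the file headers, and no position came from the RefSeq table. The probes stood for 27567 genes by name, of which 8929 had more than 1 probe.

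The arrays lay on 3 slides scanned on 2 days. Slide 1 held KO ventricle, KO aorta and C2C12. Slide 2 held the 3 WT arrays and C2C12. Slide 3 held KO atrium, ventricle and aorta and C2C12, and was the only slide scanned on the second day. No slide held both KO and WT, and each region had the same array position on every slide, so region and position could not be told apart. C2C12 was on all 3 slides and tied them together.

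Arrays of a group were compared before they were averaged, over 7464 bright probes. In 3 of the 16 pairs of arrays from 1 group the log2 differences (SD 0.0511 to 0.0597) were smaller than the noise between repeated spots of a probe, at 0.565 to 0.663 of it. These pairs were KO ventricle on slides 1 and 3, KO aorta on slides 1 and 3, and C2C12 on slides 1 and 3. In the other pairs the ratio was 2.82 or more. Each of the 3 pairs was averaged and counted as 1 sample. The 8 samples were then KO 1 (ventricle), KO 2 (aorta), KO 3 (atrium), WT 1 (atrium), WT 2 (ventricle), WT 3 (aorta), C2C12 1 (slides 1 and 3) and C2C12 2 (slide 2). The design had been written for every array as its own sample. The joining was chosen after the data were seen, and the fit of every array as its own sample was kept as an alternative.

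Values were log2 of the processed signal minus the 75th percentile of the same array, so 0 is the 75th percentile. Probes well above background on at least 3 of the fitted arrays were tested, with 1 probe per gene (the highest mean). The comparisons KO with WT, KO with C2C12, WT with C2C12, between regions and of genotype by region were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). KO with WT used the 6 heart samples and the comparisons with C2C12 used all 8. Benjamini-Hochberg adjusted p under 0.05 was called. Joining arrays left the genotype by region model with no residual degrees of freedom in the heart samples, so its spread came from the C2C12 pair. Every adjusted p of a gene comes from limma. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

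Where a probe was not well above background on any array of a group, the difference is a bound and is written "at least N-fold". It is the mean of the brighter group over the mean, in the dim group, of the higher of the probe's own signal and the lowest signal of any probe well above background on that array. Values near background have no order.

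Gene lists were tested with limma's camera, with a preset correlation between genes of 0.01 and with an estimated one, and with fry. Camera asks whether a list moved more than other genes. Fry asks whether its members moved, on balance, in 1 direction. Muscle scores were the mean over a list of each gene's log2 values scaled to mean 0 and SD 1, compared with an exact two-sided permutation test. The 28 lists, the rule for the genes named and the settings tried were fixed before the data were examined, apart from 2 settings added later (every array as its own sample, and the slide set as a block over the 8 samples). The lists with at least 5 tested members (26) entered camera and fry. They cover the sarcoglycan-dystrophin complex, muscle and heart genes, markers of mesoangioblasts, progenitors and other cell types, signalling pathways, stress responses, imprinted, sex-linked and HOX genes.

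The rule named 30 genes whatever their values. It also named the genes with the largest differences among called genes with non-overlapping groups, a plain symbol and signal well above background on every array of the higher group: the first 10 each way for KO with WT and the first 5 each way for the comparisons with C2C12. Further parts of the rule took the first 3 each way per region pair, the 3 with the smallest adjusted p for the interaction, and up to 4 called members per list. Lists of the first 5 genes measured in both groups were added after the data were seen, since bounds cannot be ranked. Not every gene that the rule names is given.

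The fits were tested on simulated data in which 200 genes were changed. For KO with WT over 15002 genes, 30 of 100 genes changed 2-fold and 88 of 100 changed 4-fold were called, with 6 false calls. For KO with C2C12 over 15805 genes, 18 of 100 and 71 of 100 were called, with 3 false calls. The simulated noise was independent between genes, with the same spread in every group. Genes may be correlated in the data, and far more genes were called between KO and WT (29.8%) than were changed here. The shares called and the false calls therefore need not hold for the data. The alternatives covered the background correction (normexp with offset 50), the scaling, the dim-probe filter, the choice of probe, the slide and the region as blocks, the prior, array weights, a fold threshold, and each sample left out in turn.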

Results

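Expression was measured on 11 arrays, 5 labelled KO (beta-sarcoglycan null), 3 labelled WT and 3 of C2C12, a mouse myoblast line. After arrays that differed by less than spot noise were averaged, there were 3 KO-labelled, 3 WT-labelled and 2 C2C12 samples, and each KO-labelled and WT-labelled sample stood for atrium, ventricle or aorta. Between 49 and 62% of the probes on an array were well above background. Differences are on the log2 scale, n = 3 KO-labelled and 3 WT-labelled samples unless stated, and adjusted p comes from limma. No slide held both genotypes. A fit with the slides as a block, which sets each genotype against C2C12 on its own slides, is therefore given as the slide-blocked value. The block is the difference between the 2 C2C12 samples, whose arrays differed by 2.86 to 3.01 times spot noise. It may hold a difference between these cultures as well as between slides. In that fit the SE of each gene is 2 times its SE without the block. The fit uses signals as read, also near background. For a gene given as "at least N-fold" its slide-blocked value is therefore not an exact size and may exceed the bound. Of the 58 named genes whose call the block ended, 25 had a difference at least as large as before and 33 a smaller one, so a call that ended does not show that the slide made the difference. In the comparisons between groups, where a gene was above background on a minority of the arrays of a group, its values per sample are given and no size. The comparison of regions gives sizes and names the genes not above background on every array.

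The mutation should show first in Sgcb, which encodes beta-sarcoglycan, a membrane protein of the complex that links the muscle cell to its matrix. Its brightest probe (mm8 chromosome 5, 73914512 to 73914571) read 2.99 in KO ventricle, 2.34 in KO aorta and 2.64 in KO atrium. In the WT-labelled samples it read 2.07 in atrium, 2.2 in ventricle and 1.82 in aorta, and in C2C12 2.41 and 2.82. The KO-labelled mean was thus 0.63 above the WT-labelled mean (SE 0.21, adjusted p = 0.0709, slide-blocked 1.04 with adjusted p = 0.237), and all 3 KO-labelled samples lay above all 3 WT-labelled ones. A second probe (73913028 to 73913087) differed by 0.41 (adjusted p = 0.289), and 1 more (73923289 to 73923348) was not above background on any array. Lower Sgcb in the null cells was therefore not seen, which goes against the labels. The labels do not say which part of the gene is deleted, and a probe outside the deleted part checks nothing. The samples are called KO-labelled and WT-labelled for this reason, and every direction given here rests on those labels.

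Sgce (epsilon-sarcoglycan, chromosome 6, 4624457 to 4624516) was at least 347-fold higher in the KO-labelled samples (adjusted p = 0.00011, slide-blocked log2 10.06). Sgca (alpha-sarcoglycan, chromosome 11, 94779420 to 94779479) was at least 16.1-fold higher (adjusted p = 0.000418, slide-blocked 4.85). Sgcd (delta-sarcoglycan, chromosome 11, 46824266 to 46824325) was lower by 1.17 (SE 0.18, adjusted p = 0.00562). Lama2 (laminin alpha 2) was at least 34.1-fold higher (adjusted p = 4.81e-05). Of 17 tested genes of the sarcoglycan-dystrophin complex, 8 were higher and 2 lower, or 9 and 2 adjusted over the list alone, with a median of 0.63 (slide-blocked 0.9). Camera put the list up (adjusted p = 0.0134, and adjusted p = 0.479 with an estimated correlation between genes). Without WT replicate 1 camera's adjusted p was 0.093. The slide block ended the Sgcd call (-0.97, adjusted p = 0.208).

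The samples fell into 2 sets. Across genes, which are not independent replicates, the KO-labelled samples correlated with each other at r = 0.978 to 0.989 and with C2C12 at 0.966 to 0.974. They correlated with the WT-labelled samples at only 0.853 to 0.882. A KO-labelled and a WT-labelled sample had 3994 to 4873 genes at least 2-fold apart, against 1532 to 1873 for a KO-labelled sample and C2C12. WT-labelled samples and C2C12 correlated at 0.855 to 0.872. The first principal component held 73.5% of the variance and set the 3 WT-labelled samples (122.24 to 129.8) apart from the other 5 (-83.53 to -66.89). The second held 9.46% and set WT atrium (73.48) apart from WT ventricle (-39.09) and WT aorta (-34.95).

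**Figure D1:**
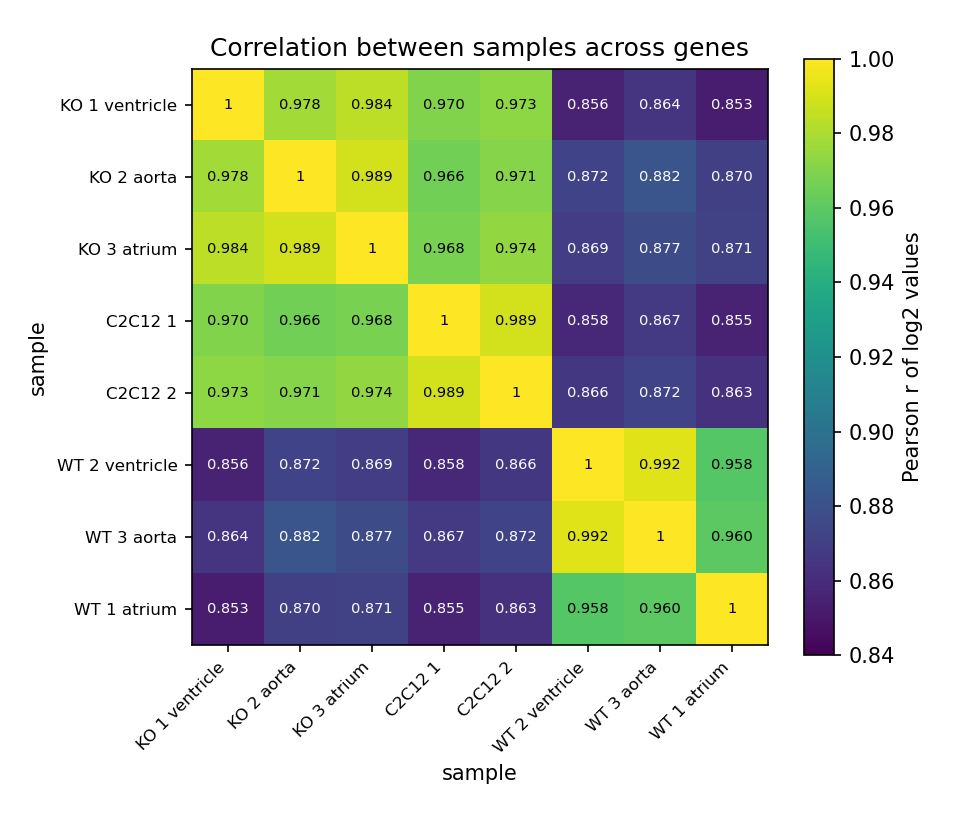
Pearson correlation across genes between the 8 samples, coloured by r. KO-labelled samples and C2C12 correlate at 0.966 to 0.974, and KO-labelled with WT-labelled samples at 0.853 to 0.882.

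The series asks why progenitors from the null heart form skeletal muscle fibres while those from the normal heart form cardiac muscle, so skeletal muscle genes come next. Myod1, a master regulator of the skeletal muscle lineage, was higher in the KO-labelled samples (2.09 to 3.05, against -5.39 to -4.8 in the WT-labelled ones, adjusted p = 3.29e-05, slide-blocked 0.00313). It was above background on 1 of 3 WT arrays. Myog (myogenin), which drives terminal differentiation, was at least 108-fold higher (adjusted p = 0.00372), and Myf5 at least 4.33-fold higher (adjusted p = 0.00147). Cdh15, the cadherin of muscle precursors, was at least 872-fold higher (adjusted p = 2.55e-05). Pax3, a regulator of embryonic muscle precursors, differed by 0.04 (adjusted p = 0.914), and Pax7, the satellite cell regulator, was above background on 1 WT and 1 C2C12 array. Of 13 myogenic regulators 6 were higher and 0 lower, or 6 and 1 adjusted over the list alone, with a median of 0.62 (slide-blocked 0.45). Camera gave adjusted p = 0.0134 upward (adjusted p = 0.479 with an estimated correlation), and adjusted p = 0.0694 without WT replicate 1. The Myog call ended with the slide block (6.73, adjusted p = 0.188).

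Among contractile genes, Chrna1 (muscle acetylcholine receptor) was higher in the KO-labelled samples (3.93 to 5.73, against -6.77 to -3.95 in the WT-labelled ones, adjusted p = 0.000399, above background on 1 of 3 WT arrays). Cacng1, a muscle calcium channel subunit, was at least 183-fold higher and the fast light chain Myl1 at least 159-fold. Embryonic myosin Myh3 was at least 71.1-fold higher (adjusted p = 0.00743). Acta1, skeletal actin, differed by 3.05 (SE 0.92, adjusted p = 0.0521), a difference that passed with the region as a block (0.0318), with median scaling (0.0411), and without KO 2 (0.0468) or WT 2 (0.0442). Of 31 tested genes 20 were higher and 2 lower, or 22 and 2 adjusted over the list alone. Their median was 3.61, or 3.4 with undetected genes at their bound, 2.86 with normexp and 1.95 with the slide block. Camera gave adjusted p = 4.96e-07 upward, and adjusted p = 0.602 with an estimated correlation of 0.69 between these genes. The slide block ended the calls of Myh3 (5.47, adjusted p = 0.303) and Myl1 (8.63, adjusted p = 0.0734).

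A muscle score was then taken per sample. The contractile score (40 genes) was 0.65 in KO ventricle, -0.43 in KO aorta and 0.01 in KO atrium, against -0.75, -0.86 and -0.83 in WT atrium, ventricle and aorta and 1.33 and 0.88 in C2C12. The means were 0.08 ± 0.54 (SD, n = 3) and -0.81 ± 0.05 (SD, n = 3), a difference of 0.89 (exact two-sided permutation p = 0.1). The myogenic regulator score (14 genes) was 0.26 ± 0.03 in the KO-labelled and -0.57 ± 0.19 in the WT-labelled samples, 0.83 apart (exact two-sided permutation p = 0.1), and 0.46 in C2C12. With 3 against 3 samples 0.1 is the smallest p possible, so neither score could pass 0.05.

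Heart genes did not all go 1 way. Nkx2-5, an early cardiac transcription factor, was at least 15.3-fold higher in the KO-labelled samples (adjusted p = 0.000142, slide-blocked 5 with adjusted p = 0.00685). Hey1 was 3.16 higher (SE 0.3, adjusted p = 0.00086) and Irx3 at least 2.57-fold higher. Gata4 was higher (-4.18 to -3.84, against -4.99 to -4.68, adjusted p = 0.0144, above background on 1 of 3 WT arrays), and Mef2c differed by -0.89 (SE 0.3, adjusted p = 0.0747). Tbx5 was not above background on any array. Among cardiac transcription factors 6 of 14 were higher and 1 lower, or 6 and 3 adjusted over the list alone (median 0.54, slide-blocked 0.65, camera adjusted p = 0.118). Leaving out KO 3 ended the Gata4 call (0.0533). Gata4 (adjusted p = 0.138) and Hey1 (1.75, adjusted p = 0.174) were not called with the slide block, nor was Gata4 with normexp (adjusted p = 0.162).

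Of cardiomyocyte genes, the light chain Myl3 (this probe at least 36.1-fold, adjusted p = 0.00547) was higher in the KO-labelled samples. The Z-disc genes Ldb3 (this probe at least 3.55-fold) and Csrp3 (at least 2.59-fold, adjusted p = 0.0387, above background on 3 of 5 KO arrays) were higher too. Tnnt2, cardiac troponin T and also a gene of immature skeletal muscle, was 3.07 higher (SE 0.47, adjusted p = 0.00536), and Actc1 differed by 2.19 (SE 0.7, adjusted p = 0.0629). The cardiac myosin Myh6 was above background only on the 2 KO ventricle arrays and the 3 C2C12 arrays. Of 15 tested cardiomyocyte genes 7 were higher and 4 lower, or 9 and 4 adjusted over the list alone. Their median was 1.75 (1.37 with bounds, slide-blocked 1.42, camera adjusted p = 0.156). Against C2C12, a myoblast line, their median was -0.55 in the KO-labelled and -1.6 in the WT-labelled samples. A higher level than in WT was thus shared with C2C12 and does not mark heart muscle here. A second Myl3 probe read -0.39. The Csrp3 call was lost when any sample but KO 2 was left out (up to 0.116), and Actc1 passed without WT 2 (0.0262). With the slide block Myl3 (5.4, adjusted p = 0.21), Csrp3 (1.46, adjusted p = 0.752) and Tnnt2 (1.96, adjusted p = 0.325) were not called.

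Mesoangioblasts are vessel-associated progenitors with pericyte markers. Anpep was higher in the KO-labelled samples (0.92 to 1.82, against -5.87 to -5.14 in the WT-labelled ones, adjusted p = 5.78e-05, above background on 1 of 3 WT arrays). Pdgfrb was 1.3 higher (SE 0.25, adjusted p = 0.0122), Angpt1 3.2 higher (SE 0.3, adjusted p = 0.000783) and Notch3 2.79 higher (SE 0.72, adjusted p = 0.0331), while Pdgfra was lower by 4.11 (SE 0.41, adjusted p = 0.00102). Cspg4 (NG2) differed by 0.46 (adjusted p = 0.15), but another probe was called lower (-1.15, adjusted p = 0.0377), and Alpl was not above background on any array. Of 9 pericyte and mesoangioblast genes 4 were higher and 2 lower, the same counts adjusted over the list alone (median 0.46, slide-blocked 0.49, camera adjusted p = 0.327). The smooth muscle genes Des (3.16 to 4.01, against -5.98 to -4.89, adjusted p = 3.81e-05, above background on 1 of 3 WT arrays), Synpo2 (4.94, adjusted p = 0.000486) and Cnn1 (3.72, adjusted p = 0.0286) were higher, and Itga8 at least 5.51-fold lower. Acta2 differed by 1.83 (adjusted p = 0.106, or 0.0409 without WT 2). Other Acta2 probes read 1.98 (adjusted p = 0.109), 1.79 (adjusted p = 0.0393) and 0.93 (adjusted p = 0.0428). Of 15 smooth muscle genes 5 were higher and 1 lower, or 8 and 3 adjusted over the list alone (median 1.83, slide-blocked 1.31, camera adjusted p = 0.071). The Notch3 call was lost without KO 1, KO 2, KO 3 or WT 3 (up to 0.0985) and the Cnn1 call without KO 2, KO 3 or WT 3 (up to 0.078). The slide block ended the calls of Pdgfrb (1.22, adjusted p = 0.246), Pdgfra (-3.68, adjusted p = 0.0586), Notch3 (3.08, adjusted p = 0.311), Cnn1 (4.35, adjusted p = 0.26) and Itga8 (-3.48, adjusted p = 0.0751). Normexp also ended the Itga8 call (-1.11, adjusted p = 0.136).

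Surface markers of progenitors were tested next. Thy1 (CD90) was at least 1290-fold lower in the KO-labelled samples (adjusted p = 0.00011, slide-blocked -10.93 with adjusted p = 0.00764), Cd34 was lower by 1.28 (SE 0.27, adjusted p = 0.0166) and Vcam1 was lower by 1.46 (SE 0.28, adjusted p = 0.0121). Nt5e (CD73) was at least 3.92-fold higher (adjusted p = 0.000915). Ly6a (Sca-1) differed by -1.38 (adjusted p = 0.151), and Kit was not above background on any array. Of 9 genes 1 was higher and 5 lower, also adjusted over the list alone (median -1.01, slide-blocked -0.69, camera adjusted p = 0.118, or 0.479 with an estimated correlation). The Cd34 call was lost without KO 1, KO 3 or WT 3 (up to 0.0649), and with the slide block Cd34 (-0.29, adjusted p = 0.834) and Vcam1 (-1.1, adjusted p = 0.359) were not called.

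Markers of other cell types differed gene by gene. Flt1, a VEGF receptor, was 4.7 higher in the KO-labelled samples (SE 0.7, adjusted p = 0.00483, above background on 2 of 3 WT arrays), while Erg was at least 3.36-fold lower and Egfl7 was lower by 1.87 (adjusted p = 0.0212). Pecam1 was not above background on any array. Among 5 endothelial genes 1 was higher and 2 lower, also adjusted over the list alone (median -0.15, slide-blocked -1.6, camera adjusted p = 0.779). The macrophage lysozyme Lyz2 was at least 44.9-fold lower (adjusted p = 9.73e-05) and C1qb was lower by 0.68 (adjusted p = 0.0202), and Ptprc was not above background on any array. Among 6 blood and macrophage genes 0 were higher and 2 lower, or 0 and 4 adjusted over the list alone (median -0.72, slide-blocked -0.13, normexp -0.05, camera adjusted p = 0.156). The epicardial regulator Bnc1 was at least 62.8-fold lower (adjusted p = 0.00106) and Krt19 at least 1.24-fold higher (adjusted p = 0.0234, above background on 3 of 5 KO arrays). Among 5 epicardial and mesothelial genes 1 was higher and 1 lower, or 1 and 2 adjusted over the list alone (median -0.04, slide-blocked -0.28, camera adjusted p = 0.77). That median flipped to 0.07 with median scaling and 0.04 with normexp. Calls were lost without 1 sample for Egfl7 (KO 1, KO 3, WT 2 or WT 3, up to 0.0738), C1qb (KO 1, KO 2, WT 2 or WT 3, up to 0.0832) and Krt19 (KO 3 or WT 3, up to 0.0795). Of these genes, Lyz2 alone stayed called with the slide block (-5.83, adjusted p = 0.00967). The others were then Flt1 4.11 (adjusted p = 0.173), Erg -3.52 (0.0902), Egfl7 -1.6 (0.371), C1qb -0.12 (0.878), Bnc1 -7.54 (0.0536) and Krt19 2.58 (0.123). With normexp the C1qb difference was 0 and Erg (-0.81, adjusted p = 0.25) and Krt19 (0.89, adjusted p = 0.174) were not called.

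Of the matrix genes, Tgfbi, a secreted protein induced by TGF-beta, was lower in the KO-labelled samples (adjusted p = 0.0027). It read 3.66 to 4.27 in the WT-labelled samples, -2.3 in KO aorta, -6.4 in KO ventricle and -6.66 in KO atrium, above background on 2 of 5 KO arrays. Col4a1 was lower by 3.8 (SE 0.54, adjusted p = 0.0039), Dcn (decorin) was lower by 4.16 (SE 1.18, adjusted p = 0.0431) and Mfap5 was lower (-6.92 to -4.92, against -3.15 to -0.92, adjusted p = 0.00937, above background on 1 of 5 KO arrays). Thbs2 was 3.47 higher (SE 0.5, adjusted p = 0.00408). Of 25 fibroblast and matrix genes 8 were higher and 5 lower, or 9 and 5 adjusted over the list alone, with a median of 0.59, a mean of 0.12 and a slide-blocked median of 0.87 (camera adjusted p = 0.145, up). In TGF-beta and BMP signalling, Id4 was at least 133-fold lower, Fst (follistatin) was lower by 4.4 (adjusted p = 0.00319) and Bmp4 3.95 higher (SE 0.41, adjusted p = 0.00115, above background on 2 of 3 WT arrays). Of 25 genes of that list 4 were higher and 9 lower, also adjusted over the list alone (median -0.55, slide-blocked -1.42, camera adjusted p = 0.118). The Dcn call was lost when any sample but WT 1 was left out (up to 0.127). With the slide block Thbs2, Id4 and Bmp4 stayed called, and Fst (-5.43, adjusted p = 0.0545), Col4a1 (-4.11, adjusted p = 0.0927), Dcn (-4.62, adjusted p = 0.354), Tgfbi (adjusted p = 0.0915) and Mfap5 (adjusted p = 0.342) did not, and normexp also ended the Mfap5 call (adjusted p = 0.111).

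Interferon genes were the list with the lowest camera p. Mx2, an antiviral GTPase, was at least 155-fold lower in the KO-labelled samples (adjusted p = 6.69e-05, slide-blocked -9.81 with adjusted p = 0.00287). Usp18 was at least 85.2-fold lower (adjusted p = 3e-04), Oas1a at least 52.8-fold lower (adjusted p = 0.000819) and Oasl1 was lower by 6.42 (SE 0.62, adjusted p = 0.000934, above background on 4 of 5 KO arrays). Of 28 genes 1 was higher and 24 lower, or 1 and 26 adjusted over the list alone, with a median of -3.6 (-3.38 with bounds, slide-blocked -3.17, normexp -2.25). Camera gave adjusted p = 7.67e-11 downward, and adjusted p = 0.479 with an estimated correlation. The C2C12 samples lay with the KO-labelled ones, since the median KO-labelled minus C2C12 was 0.03 and WT-labelled minus C2C12 3.37. Among inflammatory genes, Il1rl1 (the IL-33 receptor) was lower by 7.49 (SE 1.03, adjusted p = 0.00355), complement C3 was lower by 6.09 (SE 1.08, adjusted p = 0.00904), Ccl5 was lower by 4.85 (SE 0.71, adjusted p = 0.00453) and Cxcl5 at least 6.45-fold higher (adjusted p = 0.00063). Of 18 genes 1 was higher and 11 lower, also adjusted over the list alone (median -1.41, slide-blocked -2.23). Camera gave adjusted p = 0.0134 downward (adjusted p = 0.479 with an estimated correlation). The slide block ended the calls of Il1rl1 (-7.68, adjusted p = 0.1) and C3 (-6.61, adjusted p = 0.158).

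In the Notch pathway, Heyl was at least 87-fold, Jag2 at least 45-fold and Dll1 at least 5.61-fold higher in the KO-labelled samples (adjusted p = 0.000785, 3.89e-05 and 0.00806). Of 14 genes 6 were higher and 1 lower, or 6 and 3 adjusted over the list alone (median 0.34, slide-blocked 0.44, camera adjusted p = 0.119). In the Wnt pathway, the transcription factors Tcf7 (at least 44.2-fold) and Lef1 (at least 40.1-fold) were higher, and Sfrp1 (at least 24.5-fold) and Wnt5a (at least 3.2-fold) lower. Of 24 genes 8 were higher and 3 lower, or 9 and 3 adjusted over the list alone. The Wnt median was -0.12, the mean 0.41, camera pointed up (adjusted p = 0.411), the slide-blocked median was 0.09 and the normexp median 0.06. Pparg, the adipocyte regulator, was 4.71 higher (SE 0.25, adjusted p = 8.9e-05) and Fabp4 was lower (-6.1 to -4.59, against -3.62 to -2.51, adjusted p = 0.0258, above background on 2 of 5 KO arrays). Among 4 adipocyte genes 1 was higher and 1 lower, also adjusted over the list alone (median 1.2, slide-blocked 1.23, too few for camera). Of cartilage and bone genes, Sox9 was lower by 2.01 (SE 0.23, adjusted p = 0.00164), Sox5 at least 2.75-fold lower, Col2a1 2.13 higher (adjusted p = 0.0265) and Spp1 0.75 higher (adjusted p = 0.0252). Among 8 of them 2 were higher and 2 lower, or 2 and 3 adjusted over the list alone (median -0.34, slide-blocked -0.07, camera adjusted p = 0.498). The median flipped to 0.28 with normexp, and another Col2a1 probe was called lower (-1.31, adjusted p = 0.0221). Calls were lost without 1 sample for Fabp4 (KO 3, WT 2 or WT 3, up to 0.0824), Col2a1 (KO 1, KO 2, KO 3 or WT 3, up to 0.0848) and Spp1 (KO 1, KO 2, KO 3 or WT 3, up to 0.0882). With the slide block Dll1 (3.14, adjusted p = 0.327), Col2a1 (2.55, adjusted p = 0.24), Spp1 (0.95, adjusted p = 0.211) and Fabp4 (adjusted p = 0.491) were not called, and normexp ended the calls of Wnt5a (-0.7, adjusted p = 0.248), Sox5 (-0.63, adjusted p = 0.328), Fabp4 (adjusted p = 0.444) and Spp1 (0.62, adjusted p = 0.0968).

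Growth and stress genes included Cdkn2b and p53 targets. Cdkn2b, an inhibitor of the cell cycle, was at least 170-fold lower in the KO-labelled samples (adjusted p = 1e-05), whereas Gdf15 (1.5 to 2.42, against -6.85 to -4.65, adjusted p = 0.000558, above background on 1 of 3 WT arrays), Pmaip1 (at least 35-fold) and Cdkn1c (at least 3.2-fold) were higher. Of 19 cell cycle inhibitors and p53 targets 4 were higher and 1 lower, also adjusted over the list alone (median 0.27, slide-blocked 0.05, normexp 0.16, camera adjusted p = 0.315 up, fry down). Of 31 cell cycle genes 2 were higher, Ccnb2 (1.36, SE 0.27, adjusted p = 0.0124) and Bub1b (0.99, SE 0.18, adjusted p = 0.0104), and 0 lower, also adjusted over the list alone. The cell cycle median was 0.03 (slide-blocked 0.01, camera adjusted p = 0.571) and flipped to -0.03 in the deposited table and -0.04 with normexp. Egln3 (at least 68.7-fold), Slc2a3 (at least 18-fold) and Ndrg1 (2, adjusted p = 0.0171) of the hypoxia and glycolysis list were higher, and Adm was lower by 4.76 (SE 0.3, adjusted p = 0.000159). Of its 22 genes 6 were higher and 1 lower, also adjusted over the list alone (median 0.22, slide-blocked 0.73, camera adjusted p = 0.118). Atf4 (1.07, adjusted p = 0.0163) and Xbp1 (1.04, adjusted p = 0.0096) were the 2 of 16 ER and amino acid stress genes that were higher, and 0 were lower, also adjusted over the list alone (median 0.47, slide-blocked 0.86, camera adjusted p = 0.145). The Ndrg1 call was lost without KO 1, KO 3 or WT 3 (up to 0.0558) and the Atf4 call without WT 2 (0.0543). The slide block ended the calls of Cdkn1c (2.44, adjusted p = 0.132), Ccnb2 (1.63, adjusted p = 0.155), Bub1b (1.06, adjusted p = 0.175), Ndrg1 (2.54, adjusted p = 0.163), Atf4 (1.42, adjusted p = 0.145) and Xbp1 (1.5, adjusted p = 0.0831).

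Of immediate early genes, Nr4a1 was lower by 2.31 (adjusted p = 0.00552), Ier3 was lower by 1.66 (adjusted p = 0.00579) and Fosl1 was lower by 1.38 (adjusted p = 0.0485) in the KO-labelled samples, and Egr2 was 2.33 higher (adjusted p = 0.00803). Among 17 genes 1 was higher and 4 lower, or 1 and 5 adjusted over the list alone (median -0.05, slide-blocked -0.13, camera adjusted p = 0.59). That median was 0.06 with median scaling. Ppargc1a, a regulator of mitochondria, was lower (-5.7 to -5.37, against -2.22 to -1.81, adjusted p = 8.24e-05, above background on 1 of 5 KO arrays) and Sdhc 0.69 higher (adjusted p = 0.0287). Among 22 oxidative phosphorylation genes 1 was higher and 1 lower, or 0 and 1 adjusted over the list alone (median -0.01, slide-blocked -0.05, camera adjusted p = 0.894), and the median was 0.09 with median scaling. The imprinted gene H19 was 7.18 higher (SE 0.82, adjusted p = 0.00176) and Igf2r was lower by 5.74 (SE 0.72, adjusted p = 0.00246, above background on 4 of 5 KO arrays). Of 10 imprinted genes 3 were higher and 2 lower, also adjusted over the list alone (median 1.01, slide-blocked 1.13, normexp 0.64, camera adjusted p = 0.315). Calls were lost without 1 sample for Fosl1 (any but KO 2, up to 0.138) and Sdhc (any but WT 1, up to 0.0962). With the slide block Ppargc1a stayed called (adjusted p = 0.015), and Nr4a1 (-3.39, adjusted p = 0.0503), Ier3 (-1.85, adjusted p = 0.112), Fosl1 (-2.22, adjusted p = 0.197), Egr2 (1.85, adjusted p = 0.27), Sdhc (0.62, adjusted p = 0.392), H19 (6.83, adjusted p = 0.0741) and Igf2r (-5.86, adjusted p = 0.0784) did not, and normexp also ended the Sdhc call (0.64, adjusted p = 0.0633).

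HOX genes mark the position along the body from which a cell derives. Hoxa11 (at least 89.2-fold, adjusted p = 2.9e-05) and Hoxc10 (at least 33.9-fold, adjusted p = 3.81e-05) were higher in the KO-labelled samples, and Hoxb2 (at least 27.7-fold, adjusted p = 2.69e-05) and Hoxb9 (at least 44.3-fold, adjusted p = 0.000298) lower. All 4 stayed called with the slide block. Of 18 HOX genes 6 were higher and 7 lower, or 7 and 8 adjusted over the list alone, with a median of -0.17 (slide-blocked 0.17, normexp 0.04, camera adjusted p = 0.894). Xist, which is made from the inactive X chromosome of female cells, was at least 278-fold higher (adjusted p = 2.66e-05, slide-blocked 9.04) and near its C2C12 level (0.72 above it). It was the 1 tested gene of the sex-linked check, called also adjusted over the list alone (median 10.29, 8.12 with its bound, too few for camera), and Ddx3y of the Y chromosome was not above background on any array. Sfmbt2 was at least 4.19-fold lower (adjusted p = 0.000974), a call that ended with normexp (-0.97, adjusted p = 0.173). Its other probes were not above background on any array, so the call rests on this probe alone.

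Over the 26 lists camera called 3 up and 2 down with the preset correlation, and with an estimated correlation none of these calls held (adjusted p from 0.479 to 0.931 over all lists). Fry, which asks whether the members of a list moved on balance 1 way and compares no list with other genes, called 10 up and 6 down.

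**Figure D2:**
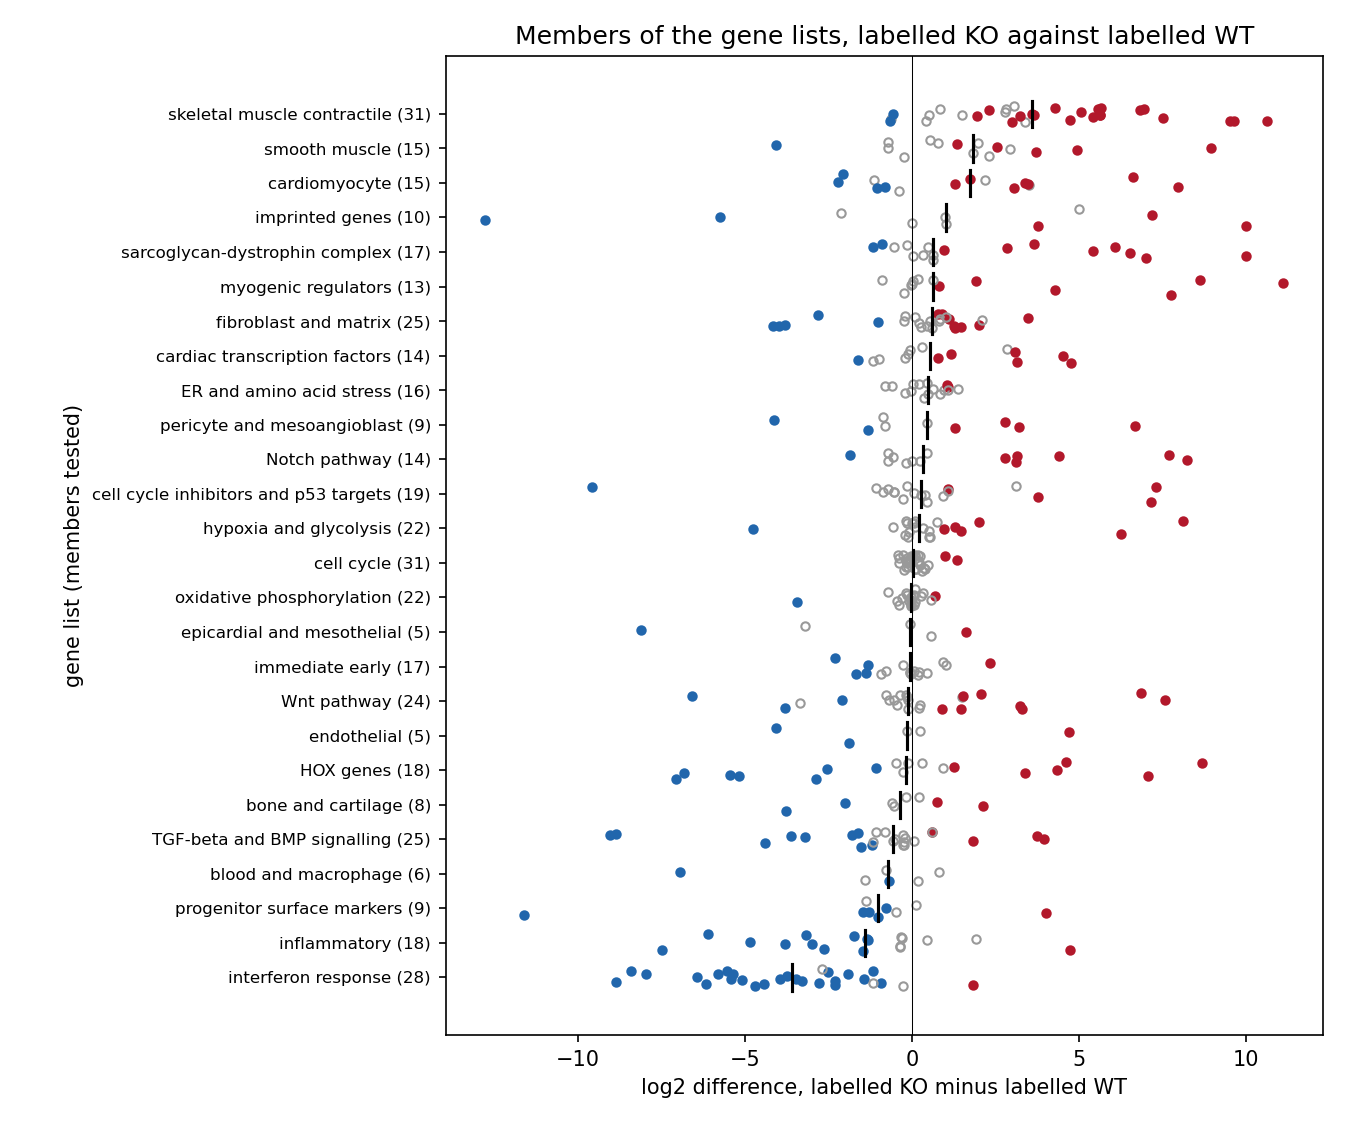
KO-labelled minus WT-labelled log2 difference of each member of 26 gene lists, filled where limma's adjusted p is under 0.05, with a bar at each list's median. The contractile median is 3.61 and the interferon median -3.6, and the sign of the Wnt and HOX medians changes with the slide block.

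Over all 15002 genes tested, 2061 were higher and 2405 lower in the KO-labelled samples, 29.8% of the genes. Of these 2850 were at least 2-fold apart, and in 49.3% of all genes tested the groups did not overlap, where chance gives 10%. With the slide block 514 were higher and 383 lower. The counts fell by more than 1.5-fold without KO 2 (1347 higher, 1586 lower), KO 3 (1306 and 1437), WT 3 (1350 and 1298) and, for lower genes, WT 2 (1295). The median difference of all genes was -0.06, against -0.11 in the deposited table, -0.04 with quantile scaling, 0.05 with median scaling and 0.03 with normexp, and it was not taken off the values of single genes. Among named genes, the region block ended the calls of C1qb, Cnn1, Csrp3, Krt19, Sdhc and Spp1 (adjusted p from 0.0516 to 0.082), and with it Acta1 (0.0318), Cfhr2 (0.0133), H2bu2 (0.0224), Pag1 (0.00657), Serpinb2 (0.0126) and Thbs1 (0.0058) passed. Quantile and median scaling ended those of C1qb (0.0529 and 0.0728) and Fosl1 (0.053 and 0.0621), and with median scaling Acta1 (0.0411) and Actc1 (0.0453) passed.

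Single genes were then taken by the naming rule. Towards the KO-labelled samples, the synaptotagmin Syt13 (this probe at least 979-fold), the RNA-binding Khdrbs3 (at least 561-fold), the muscle membrane gene Bves (at least 490-fold), Tmem37 (this probe at least 455-fold), the growth factor binder Igfbp5 (at least 442-fold), Xlr4b (at least 303-fold) and the glycogen-binding Stbd1 (at least 259-fold) were higher, beside Cdh15, Chrna1 and Xist. Towards the WT-labelled samples, Dlk1, an imprinted Notch ligand relative, was called lower in the KO-labelled samples (adjusted p = 0.000165, with the slide block 0.0103). It read 6.47 to 6.75 in the WT-labelled samples, -4.21 in KO aorta, -7.37 in KO ventricle and -6.81 in KO atrium, with 2 of 5 KO arrays above background. Irx1 (at least 567-fold), Ripk3 (at least 352-fold), Rnf130 (at least 308-fold), Thumpd1 (this probe at least 241-fold), Lgalsl (at least 223-fold) and the natural killer receptors Klra1 (at least 210-fold) and Klra7 (at least 207-fold) were also lower in the KO-labelled samples, beside Thy1. All of these stayed called with the slide block and with each sample left out. Among genes above background in both groups, chosen after the data were seen, Crip1 (8.36), the precursor filament gene Nes (8.09), Klhl30 (7.68) and Crip2 (7.22) were among the highest in the KO-labelled samples. Il1rl1, Il11ra1 (-6.73), C3, Bckdhb (-5.91), Nrn1 (-5.83) and Lrfn3 (-5.52) were among the lowest, and the rule had passed over C3 for the form of its symbol. The slide block ended the Nrn1 call (-6.03, adjusted p = 0.0606).

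**Figure D3:**
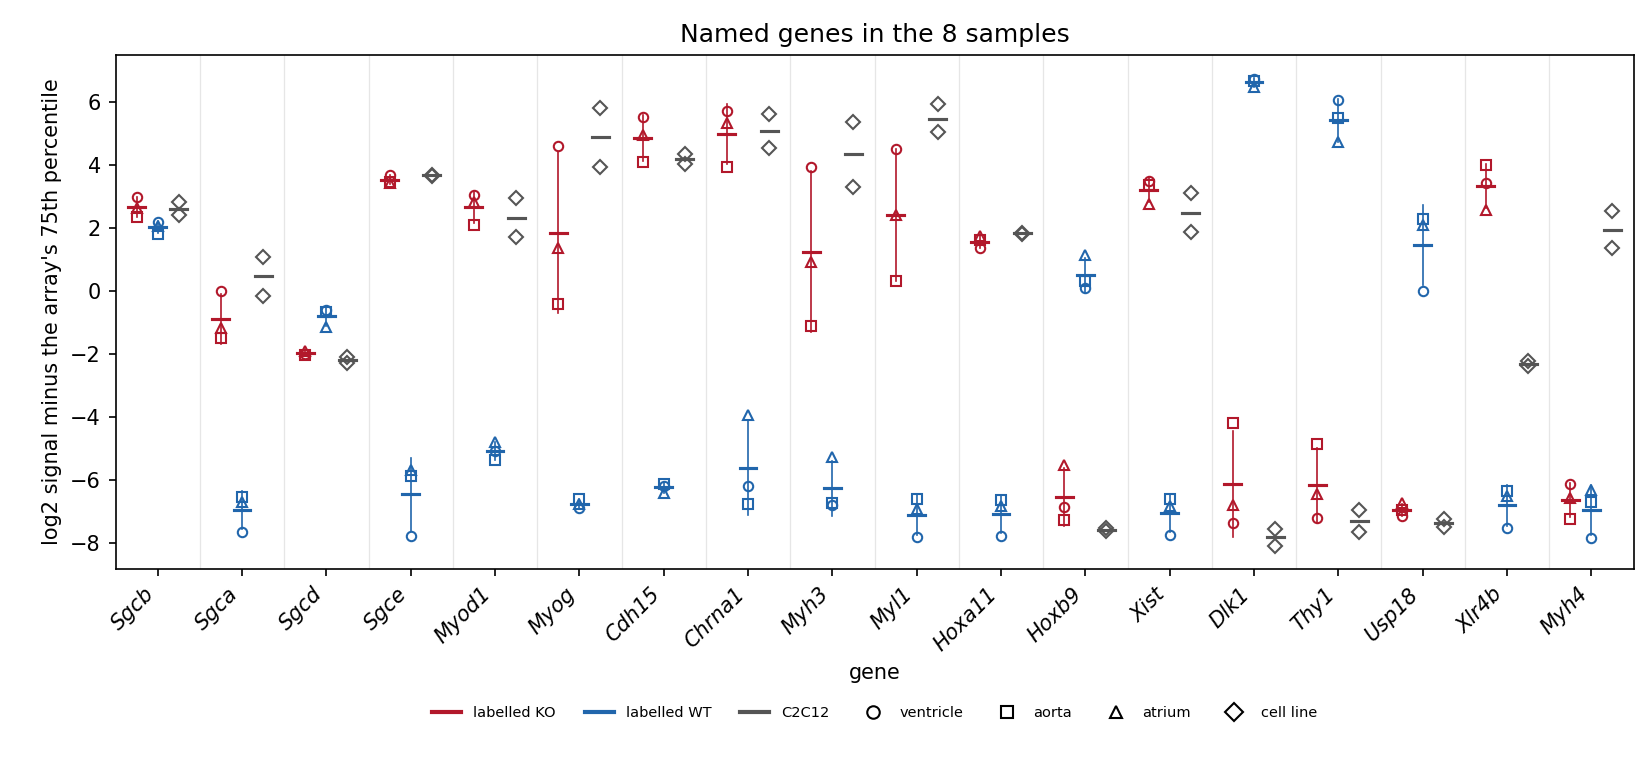
log2 signal relative to the array's 75th percentile for 18 genes in each sample, with a bar at the group mean and a line for the SD of the 3 KO-labelled and 3 WT-labelled samples. Sgcb means are 2.66 and 2.03, and Myod1 means 2.66 and -5.1.

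C2C12 was the control for muscle differentiation, so each genotype was set against it (n = 2 C2C12 samples). Adult and perinatal myosins were among the genes lower in the KO-labelled samples. Myh4 was at least 120-fold lower (adjusted p = 0.00206), Myh8 was lower (-7.02 to -2.52, against 2.5 and 2.92 in C2C12, adjusted p = 0.0371), as was Myh1 (-7.31 to -3.8, against 0.84 and 2.45, adjusted p = 0.0272). The Wnt inhibitor Sfrp2 (-5.27 to -4.24, against 0.36 and 0.66, adjusted p = 0.00206) and Akip1 (-7.38 to -4.47, against -0.04 and -0.06, adjusted p = 0.0217) were lower too. Myh8, Myh1, Sfrp2 and Akip1 were each above background on 2 of 5 KO arrays. Higher than in C2C12 were the X-linked Xlr4b (5.66, SE 0.48, adjusted p = 0.00476) and Xlr3c (5.42, SE 0.42, adjusted p = 0.00312), Slc25a13 (-1.16 to -0.19, against -5.62 and -5.27, adjusted p = 0.00499, above background on 1 of 3 C2C12 arrays), Tex101 (at least 14.1-fold) and Slitrk6 (at least 7.75-fold). Myod1 differed by 0.33 (adjusted p = 0.853), Cdh15 by 0.66 (adjusted p = 0.564) and Myog by -3.03 (adjusted p = 0.417). Of 15805 genes 105 were higher and 94 lower, 1.26% of the genes. The counts were 276 and 190 without WT 1, 67 and 61 without KO 1, 36 and 30 without KO 3, and 65 and 44 without WT 3. Without KO 2, 54 genes were higher. Without C2C12 1 they were 7 and 6 and without C2C12 2 they were 11 and 7, so they rest on the C2C12 pair. With the slide block they were 16 and 11. Against the C2C12 array of the same slide, Xlr4b was 6.1 on slide 1 and 5.76 on slide 3. KO ventricle, KO aorta and C2C12 were within spot noise between these slides, so the slides are not independent.

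The WT-labelled samples were set against C2C12 in the same way. Over the 31 contractile genes the median WT-labelled minus C2C12 difference was -6.67, with no list test run for this comparison. Among the genes of the naming rule, Myl1 was at least 1340-fold, Myog at least 881-fold, Syt13 at least 844-fold (this probe), Tmem37 at least 653-fold (this probe) and Bves at least 553-fold higher in C2C12. Dlk1 was at least 4590-fold, Thy1 at least 1990-fold, Irx1 at least 851-fold and Rnf130 at least 459-fold higher in the WT-labelled samples. Among genes above background in both, chosen after the data were seen, Tnnc2 (-9.33), Mylpf (-8.46), Crip1 (-8.33), Nes (-8.15) and H19 (-8.03) were among the lowest against C2C12. Grb14 (6.89), Klra13-ps (6.89), Nrn1 (6.69), Tmem176b (6.43) and Oasl1 (6.4) were among the highest. Of 15805 genes 2162 were higher and 2098 lower, 27% of the genes. Without C2C12 1 the counts were 1160 and 1112 and without C2C12 2 they were 1203 and 1161, and without WT 3 there were 1440 higher. The slide block gave 1157 and 1128. Slide 2 held all 3 WT arrays and 1 C2C12 array. The counts without C2C12 1 rest on that single C2C12 array, and no gene is called from them.

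The differences of the KO-labelled samples and of C2C12 from WT went together, with the same WT-labelled samples in both. Across genes r was 0.913 and the covariance 2.45. When the 3 groups were simulated without differences, the shared WT-labelled samples alone gave r = 0.453, a covariance of 0.0624 and 0 genes called in both. With nothing changed that 0 was fixed in advance. It does not show how far shared samples raise the overlap where separate differences exist. In the fit of all 8 samples over 15805 genes, 1659 of 2356 and 2098 genes were higher in both (313 by chance), 1750 of 2759 and 2162 lower in both (377 by chance) and 4 called in opposite directions. With 3 WT-labelled samples these could not be divided between the comparisons, so part of the excess may come from the shared controls.

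Region was compared over both genotypes, and no gene passed. Between ventricle and aorta the first genes by p were Hoxaas2 (1.85), the junction gene Patj (1.69, SE 0.21) and Islr (1.47) upward and Serpinb2 (-2.38), Pag1 (-1.15) and Klf10 (-0.93) downward, each with adjusted p = 1. Between atrium and aorta they were H2bu2 (1.96, adjusted p = 0.713), the matrix gene Thbs1 (1.71, SE 0.24, adjusted p = 0.508) and Fuca2 (0.91) upward. Downward were Acot1 (-2.28, SE 0.18, adjusted p = 0.388), the adaptor Pag1 (-2.18, adjusted p = 0.388) and Sema5a (-1.69, adjusted p = 0.508). Between atrium and ventricle Thbs1 (1.77), Ifitm10 (1.66) and the natriuretic peptide Nppb (1.08, SE 0.17) were higher and Cfhr2 (-2.89), Dlx4 (-2.38) and Acot1 (-2.36) lower, each with adjusted p = 0.56. Limma called 0 genes by the F test (719 at unadjusted p under 0.05), 0 for ventricle against aorta (440), 0 for atrium against aorta (675) and 0 for atrium against ventricle (1147). Without KO 3, the KO atrium sample, 122 genes were called for atrium against either region, with WT atrium then the only atrium sample. Hoxaas2, Patj, Pag1, H2bu2, Acot1, Dlx4 and Cfhr2 were not above background on every array, so their sizes are not exact and their order decides nothing. Region and array position were the same on every slide and were not separable.

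The interaction asks whether regions differed otherwise in the KO-labelled than in the WT-labelled samples. The smallest adjusted p, 0.213, was shared by Mest, an imprinted gene, Fhl1, a muscle LIM protein, and Rbfa, a mitochondrial ribosome factor. Their atrium minus aorta difference was 10.16, 7.27 and 7.4 larger in the KO-labelled samples, and their ventricle minus aorta difference -0.03, -0.4 and 0.01. WT atrium read -6.9 for Mest, -4.31 for Fhl1 and -6.57 for Rbfa. Mest and Rbfa were above background on 2 of 3 WT arrays, so the sizes for these 2 genes are not exact. In the 6-sample fit Mest differed by 1.03 between the genotypes, or -2.47 without WT 1 (adjusted p = 0.0193). Limma called 0 of 15805 genes (1866 at unadjusted p under 0.05), with the spread taken from the C2C12 pair since each region held 1 sample per genotype.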

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

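All tests of explanations in this part, and the bounds they were held to, were chosen after the values were seen, some bounds were changed after the values were known, and the score and gene differences between regions were not tested.

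The contractile score of ventricle minus aorta was 1.08 in the KO-labelled samples and -0.03 in the WT-labelled ones. For the myogenic score ventricle minus aorta was -0.02 and 0.39 and atrium minus aorta -0.06 and 0.2 in the KO-labelled and WT-labelled samples. Mest, atrium minus aorta, was 0.31 and -9.86, and Fhl1 was 0.89 and -6.39. Mest read -6.9 in WT atrium and was not above background on every WT array, so its -9.86 is not an exact size. Each was picked out because the sign differed between the 2 genotypes, with 1 sample per region and genotype, so the difference itself was not tested. Score differences of -0.02, -0.03 and -0.06 are near 0, and their sign carries no direction. By the median log2 difference, 20 of 31 contractile genes were higher in WT ventricle than in WT aorta (median 0.13), the same sign as in the KO-labelled samples (4.15).

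The samples labelled KO resembled C2C12 and not WT, and Sgcb was not lower in them. Slide is argued against as the whole cause, since the C2C12 difference between the slides followed the genotype difference with a slope of only 0.0108. The slope was taken over the 5115 genes called between the genotypes in the fit of all 8 samples. Scan day did not follow the labels, since the KO-labelled arrays of slide 1 were scanned on the day of the WT-labelled ones. C2C12 cells in the same state are also argued against, because 199 genes were called between the KO-labelled samples and C2C12. With the slide block 27 were called, and 66 to 128 without 1 KO-labelled sample. These calls rest on only 2 C2C12 samples. A muscle programme confined to the genes of the muscle lists, in cells otherwise like WT, is argued against too. Outside these lists, 83.4% of the genes on in WT and off in C2C12 were off in the KO-labelled samples. A wider muscle programme stays open, because C2C12 is itself a muscle line and the set may hold genes that such a programme turns off. By genes 2-fold apart the KO-labelled samples and C2C12 were set apart less clearly. Such genes numbered 1532 to 1873 in KO-labelled and C2C12 pairs and 932 to 1332 within the KO-labelled samples. There were 934 in the C2C12 pair and 854 to 2764 within the WT-labelled samples. Whether the KO-labelled cells were C2C12 or a line of the same origin in another state could not be decided, since 100% of the 5 HOX genes with opposite states in WT and C2C12 (Hoxa11, Hoxc10, Hoxb2, Hoxb9 and Hoxd4) had the state of C2C12, but the shares over all genes give that with a probability of 0.231, and Xlr4b (5.66) and Xlr3c (5.42) were above C2C12. Genotype, and a progenitor of another origin in the null heart, also remain open and were not tested, and no slide held both genotypes. Xist was called higher in the KO-labelled samples, so sex or the state of the X chromosome could not be told apart from genotype. Ddx3y was not above background on any array, so the WT-labelled samples showed neither Xist nor this Y gene.

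Contractile genes were highest in KO ventricle and lowest in KO aorta, with 30 of 31 tested genes higher in ventricle and a median of 4.15 (SD 1.57). Array position is argued against as the whole cause for the 14 of these genes that were above background in WT ventricle and WT aorta, since they differed between these positions by a median of 0.29 in the WT-labelled samples (SD 0.53) and 3.27 in the KO-labelled ones. For the other 17 it stays open, because values near background in the WT-labelled samples (median 0.12) could not show it. Extent of differentiation may differ between the cultures and could not be decided, because the cell cycle list changed by a median of only -0.17 (SD 0.48). Region is the same as array position here, so what these values say of position holds equally for a region effect shared by both genotypes. A region effect in the KO-labelled samples alone rests on 1 sample per region and stays open.

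WT atrium stood apart from the other WT-labelled samples, with 2764 genes at least 2-fold from another of them. A weaker array is argued against, since 49.8% of its probes were well above background, beside 49.4 in WT aorta, 49 in KO atrium and 57.1 in WT ventricle. Atrium or its array position is argued against as a cause shared by both genotypes. The KO atrium deviation followed the WT atrium one with a slope of only 0.0529 over 2435 genes. An effect of atrium in the WT-labelled cells alone stays open, because the KO-labelled samples resembled C2C12 and not WT and may not show it. Lower p53 activity could not be decided, since other lists lay about as low. The list of cell cycle inhibitors and p53 targets had a median of -1.09 in WT atrium (13 of 19 genes lower). That was at percentile 0 of 10000 random lists of matched level. The smooth muscle list (-1.02) was at percentile 0 too, and the endothelial (-1.15), fibroblast and matrix (-0.51) and ER stress (-0.57) lists at 0.7, 0.01 and 0.01. The cause stays open with 1 sample.

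The genes called between the KO-labelled and WT-labelled samples numbered 4466. Of the 10 splits of the 6 samples into 3 and 3, 1 gave as many, the real one, and the highest other split gave 0. The splits are too few for a share under 0.05.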

How the results depend on the processing

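The joining of near-identical arrays into 8 samples, on which the main values rest, was chosen after seeing the data, as was the slide set as a block over those samples. Every array as its own sample, as the design had it, thereby became an added setting. The other settings were planned, for arrays that were not yet joined. Slide as a fixed block over 11 arrays and as a random block were fitted on unjoined arrays. Repeats of a sample on different slides count as replicates there, so larger counts in those fits are not slide-adjusted results of the 8 samples. Where no reason is given, the cause was not tested.

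Under the other settings 1811 of 1984 values for the 160 named genes kept their call, 151 were no longer called, 17 became called and 5 reversed. A change of sign counted as a reversal only where the main fit or the other setting called the gene. Values called in neither may therefore have changed sign among those kept, and the same rule was used for the lists. For the 26 lists 344 of 382 values kept their call, 7 were no longer called and 31 became called. Among the 137 named genes called between KO-labelled and WT-labelled samples, 135 stayed called with quantile scaling, 135 with median scaling, 136 in the deposited table, 124 with normexp, 131 with the region as a block and 79 with the slide set as a block. Of them 117 stayed called whichever sample was left out. The reversals were C1qb with normexp (0, adjusted p = 1), Mest without WT replicate 1 (-2.47, where the values with a sample left out ran up to 3.1), and other probes of Col2a1 (-1.31), Cspg4 (-1.15) and Myl3 (-0.39). Of 53 values from other probes, 50 kept the call.

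For KO-labelled against WT-labelled samples the main counts were 2061 higher and 2405 lower. Slide as a fixed block over 11 arrays gave 1240 and 1283, and the slide set as a block 514 and 383. Slide as a random block over 8 arrays gave 5833 and 7070. Its estimated correlation was negative (-0.468), since near-identical arrays lay on different slides, which narrows the errors. The KO arrays of slide 1 only gave 797 and 1353. Normexp gave 1242 lower, probes above background on all arrays 1346 higher (fewer genes tested) and array weights 3444 and 3921. A log2 difference of at least 1 gave 1424 lower, treat 1069 and 1023, and every array as its own sample 3634 lower, where repeats of a sample count as replicates. Leaving out 1 sample gave 1306 to 2913 higher and 1295 to 2963 lower. The region as a block (the replicate block) gave 1746 and 1906, within 1.5-fold, and 3 lists up and 2 down. The share of calls that were higher was 46.1%, 48.3% with quantile scaling, 55.6% with median scaling, 55.5% with normexp and 41.8% in the deposited table.

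For KO-labelled samples against C2C12 the main counts were 105 and 94. Slide as a fixed block gave 473 and 416 and as a random block over 11 arrays 864 and 748, where repeats of a sample count as replicates. The slide set as a block over the 8 samples gave 16 and 11. Normexp gave 31 and 14 and moved the higher share from 52.8% to 68.9%. No filter gave 58 and 42, above background on all arrays 35 and 25, and every array as its own sample 855 and 774. Leaving out 1 sample gave 7 to 276 and 6 to 190.

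For WT-labelled samples against C2C12 the main counts were 2162 and 2098. Slide as a random block gave 3970 and 3581, normexp 1051 higher, above background on all arrays 1314 lower, every array as its own sample 3473 and 3188 and the slide set as a block 1157 and 1128. With 1 sample left out they were 1160 to 2750 and 1112 to 2874.

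For region, slide as a random block called 75 genes by the F test, 24 for ventricle against aorta, 69 for atrium against aorta and 48 for atrium against ventricle. Repeats of a sample count as replicates in that fit, and its estimated correlation was negative (-0.456). Every array as its own sample called 122, 72, 65 and 50. Leaving out 1 sample gave 0 to 122 for both atrium comparisons and 0 for the F test and ventricle against aorta. The interaction called 129 genes with trend and robust and 10907 with every array as its own sample, since the spread then came from near-identical arrays. The interaction without each sample was not run, since a region would lose its only sample of a genotype, nor was the slide as a random block. C2C12 as a further group in the interaction is the fit reported.

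Of the 26 lists 3 were up and 2 down. Camera with the estimated correlation gave 0 and 0 (sarcoglycan-dystrophin complex 0.479, myogenic regulators 0.479, contractile 0.602, interferon 0.479, inflammatory 0.479), and fry 10 and 6. Normexp gave 5 and 4, no filter 7 up and the slide set as a block 6 up. With 1 sample left out, 1 to 6 were up and 2 to 3 down. The adjusted p then ran from 0.00397 to 0.093 for the sarcoglycan-dystrophin complex, 0.0043 to 0.0694 for myogenic regulators, 2.46e-12 to 0.000148 for contractile genes, 4.54e-11 to 9.59e-06 for interferon and 0.00413 to 0.0159 for inflammatory genes. The 2 values above 0.05, and the 1 list up, were without WT replicate 1, 6 lists were up without KO replicate 2 and 5 without WT replicate 2. The myogenic score difference was 0.99 with normexp and 0.53 with no filter. As mean log2 without scaling it was 2.48 and that of the contractile score 3.34, another unit. With a sample left out it was 0.76 to 0.96 for the myogenic and 0.61 to 1.08 for the contractile score.

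Signal over background limits these values, since 49 to 62% of probes were well above it and folds of dimmer genes are bounds.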

Other observations

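The sets of genes below, and the counts of genes on and off, were chosen after the data were seen, and no test was run on them.

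A gene was counted as on in a group when it was well above background on every array of the group and as off when it was so on none. Of 182 genes on in the WT-labelled samples and off in C2C12, 152 (83.5%) were off in the KO-labelled samples and 4 were on. Of 546 genes off in the WT-labelled samples and on in C2C12, 344 (63%) were on in the KO-labelled samples and 31 were off. The KO-labelled samples had 16 genes on that were off in both other groups, among them Tex101, Slitrk6, Coro2a, Cxadr, Myb and Dhh, and 19 genes off that were on in both.

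In WT atrium Efemp1 was lower by 8.92 than the mean of WT ventricle and WT aorta, Uchl1 was lower by 6.95, Glipr1 was lower by 6.05 and Bok was lower by 5.5, while Eva1a was 5.76 and Aqp1 3.81 higher. Of the p53 targets, Trp53inp1 was lower by 5.48, Cdkn1a was lower by 3.59, Ccng1 was lower by 3.18, Zmat3 was lower by 3.03 and Mdm2 was lower by 1.9. The smooth muscle list had a median of -1.02 there (12 of 15 genes lower), the cell cycle list 0.4 (5 of 31 lower) and the interferon list 0.6 (7 of 28 lower). These are values of 1 sample.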
